A study of Mus musculus with 6 samples.

How the data were processed

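RNA from lung B cells of 3-month-old C57BL/6 mice, 3 WT and 3 5xFAD samples, was extracted with TRIzol after magnetic selection and freezing, and stranded libraries were made from ribosomal RNA-depleted total RNA, per the labels' protocols. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks and Cuffdiff, without roles, and the builds mm10 and GRCm38; the annotation release is not given in the sources used here. The deposited table holds 1 row per gene, with FPKM values and count values for each sample, per the file headers. The 22564 rows were taken as protein-coding genes, so non-coding genes were not analysed as a class here. At least 1 symbol, Rps18-ps3, is that of a pseudogene. The unit FPKM names a normalization for gene length and library size, and the deposited values were not rescaled for the gene lists. FPKM per count of 1 gene differed between libraries, however. Inpp5d had 190 counts and 172 FPKM in WT replicate 1, and 326 counts and 50.5 FPKM in 5xFAD replicate 1. Counts and FPKM can therefore point opposite ways. For Vav2 and Tef, edgeR log2 fold changes of 5xFAD over WT were 1.38 and 0.95. Their differences of mean log2(FPKM + 1) were -0.60 and -1.32. Member signs, sums and camera rest on FPKM, and gene calls on counts.

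The deposited count columns were read as estimated counts, since many values are not whole. Of the values of at least 0.5 steps, between 94.0% and 97.3% in a library were whole multiples of 1 step close to 1, within a tolerance of 0.05. Each column was therefore read as fragment estimates times a factor per library. Values under 0.5 steps were left out of this share. Some values lie far under a single read, which whole reads cannot give. Such values and exact zeros can be failed estimates of the authors' software; for genes with them in most libraries of 1 genotype, values per library are given in place of a fold change. Loci in the table can hold several genes, whose reads the authors' software divided. Starts of loci were raised by 1, to positions counted from 1.

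Samples were grouped by the genotype in the titles, and columns were matched to samples by the names in the descriptions. Rows that shared a symbol (162 rows on 79 symbols) were summed, giving 22481 genes. The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, trended dispersion) in R 4.3.3, over the 9651 genes with a mean of at least 1 FPKM, with genotype as the only term and Benjamini-Hochberg adjustment. The design had assumed FPKM with limma and named edgeR for the case that counts were given; limma 3.58.1 on log2(FPKM + 1) is reported as an alternative. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic.

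Of 37 fixed gene lists, 33 had at least 3 tested members and were compared with all other tested genes by limma's camera with a preset correlation of 0.01 on log2(FPKM + 1), adjusted over the 33 lists. List genes were matched by symbol, and 7 more that the table holds under an older symbol were matched by gene identifier as an alternative. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were alternatives. Single values were compared by exact permutation tests, which cannot go below 0.1 with 3 against 3 samples. Named genes were the 10 per direction with the smallest p past the threshold and without overlap of groups, filled up with the largest changes at an unadjusted p under 0.05, leaving out predicted genes and receptor segments. From each list up to 3 members at an unadjusted p under 0.05 and the 2 most abundant members were named, and App and Thy1 always; some genes that these rules select are not reported here.

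Libraries were checked for duplicates by a chi-square of counts per degree of freedom, which ran from 6.44 to 20.8 over all pairs, so no pair agreed within sampling noise. The gene test was tried on simulated counts with the means and dispersion of the 9651 genes of this comparison. Of 50 genes changed in each size, 0% were recovered at 2-fold, 14% at 4-fold, 32% at 8-fold and 46% at 16-fold, with 1 false call of 47. At this depth and spread most changes of up to 16-fold were therefore missed for single genes. The simulated counts followed the trended dispersion and held no near-zero estimates confined to 1 genotype. The 1 false call of 47 thus gives no rate of false calls among the real calls. The list test was tried on the log2(FPKM + 1) values with the difference between genotypes removed. There 1 list of random genes was raised by 1 in 5xFAD, and it was called, as were 0 of 20 unchanged lists of random genes. Random genes are not co-regulated as the fixed lists can be, so this gives no rate of false calls for the fixed lists.

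Alternatives changed the pseudocount, the filter, the scaling, the sample weights, the dispersion trend, the tool (DESeq2 1.42.0), the replicate block, the summing per symbol and the set of replicates. Further ones, chosen after seeing the data, used limma on log2(FPKM + 1), the filterByExpr filter of edgeR, counts divided by each library's step, sums over shared loci, log2 CPM and older symbols, left out Lars2 and mitochondrial genes or genes with estimates above 0 and under 0.5, and thinned counts to 1 total. Pathways named in the deposited annotation were tested with camera as well. Figures were drawn with matplotlib 3.10.9.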

Results

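Messenger RNA was profiled by RNA sequencing in B cells isolated from the lungs of 3-month-old mice of 2 genotypes, wild type (WT) and 5xFAD. The 5xFAD mouse carries human transgenes with familial Alzheimer's disease mutations, APP among them, under the Thy1 promoter and is used as a model of amyloid deposition in the brain. Each genotype was represented by 3 samples, 6 in all. The B cells had been taken from lung by magnetic selection, and the libraries were made from total RNA after ribosomal RNA depletion. The title of the series names lung B cells in relation to Alzheimer-like pathology, so the comparison asks whether the transcriptome of these cells differed between 5xFAD and WT mice. The labels do not say whether each sample came from a separate animal, so the p-values measure the spread between these samples.

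The libraries were shallow. Estimated counts over the listed genes summed to 669030, 692912 and 628581 in WT replicates 1, 2 and 3. In 5xFAD replicates 1, 2 and 3 they summed to 693172, 782297 and 706349. Lars2, the mitochondrial leucyl-tRNA synthetase gene, held between 37.5% and 45.7% of all estimated counts in every library, at 37570 ± 2427 FPKM in WT and 37630 ± 3694 FPKM in 5xFAD (SD, n = 3 each). Whether the reads counted there came from Lars2 messenger RNA was not tested. Without Lars2, totals ran from 341461 in WT replicate 3 to 466345 in 5xFAD replicate 2. Genes with at least 0.5 estimated counts numbered 9160 ± 1226 in WT and 11140 ± 645 in 5xFAD (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 samples can give). A single count corresponded to 1.28 to 1.59 CPM, which set the resolution for weakly expressed genes.

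**Figure D1:**
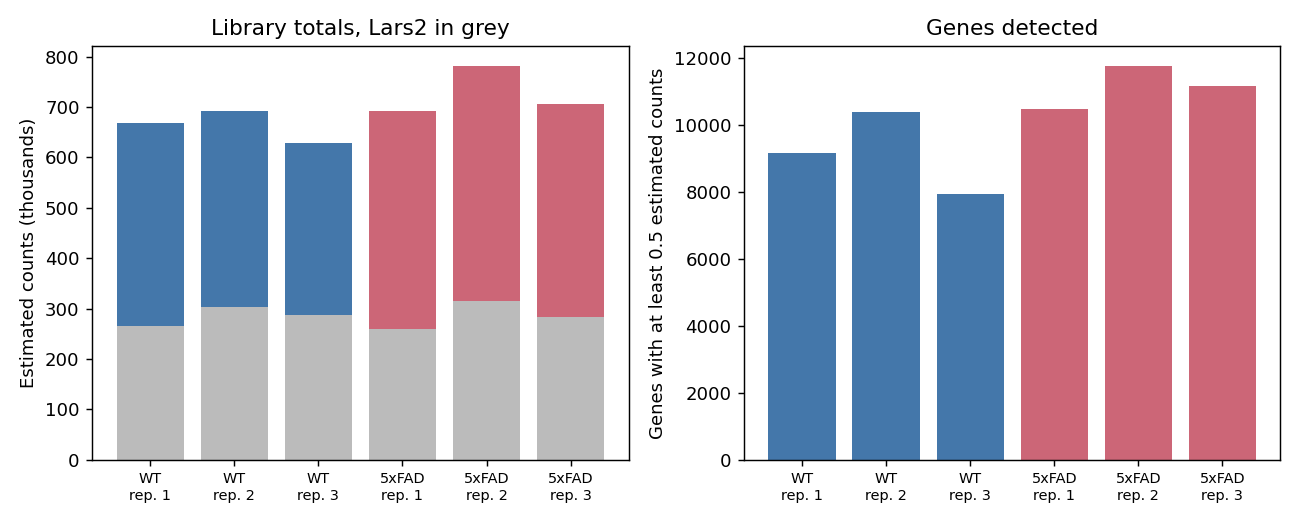
Left, total estimated counts per library, with the part held by Lars2 in grey and the rest in blue (WT) or red (5xFAD). Right, number of genes with at least 0.5 estimated counts in each library, from 7929 in WT replicate 3 to 11780 in 5xFAD replicate 2; bars are single libraries.

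Among 9651 genes tested, 10 were higher and 1 was lower in 5xFAD lung B cells. Baz1b, which encodes a bromodomain chromatin remodelling subunit also known as WSTF, was the single higher gene with more than 3 estimated counts in each library of both genotypes. It rose from 2.37 ± 0.586 FPKM in WT to 17.3 ± 5.00 FPKM in 5xFAD (SD, n = 3 each), a log2 fold change of 2.95 (SE 0.48; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00324). Its counts were 19.3, 16.2 and 26.1 in the WT libraries and 190, 201 and 129 in the 5xFAD libraries. Baz1b (ENSMUSG00000002748) lies on chromosome 5 at 135187264 to 135246129 of GRCm38.

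The 8 other higher genes described here had almost no counts in WT. Nfkb2, the p100/p52 subunit gene of the non-canonical NF-kB pathway (chromosome 19, 46303593 to 46327156), was listed at 0.00324, 0.00345 and 0.00338 estimated counts in the WT libraries and at 37.3, 69.1 and 94.5 in the 5xFAD libraries (edgeR adjusted p = 0.00301). Irf2, an interferon regulatory factor (chromosome 8, 46739745 to 46847458), had at most 0.00385 counts in WT and 28.9, 91.8 and 70.6 in 5xFAD (edgeR adjusted p = 0.00324). Slc44a2, a choline transporter-like gene (chromosome 9, 21320719 to 21355028), had at most 0.000881 counts in WT and 16.4, 175 and 72.3 in 5xFAD (edgeR adjusted p = 0.00301). Golph3, a Golgi phosphoprotein, and Dnm1l, the dynamin-related protein of mitochondrial fission, showed the same form, with 5xFAD counts of 30.3 to 79.5 and 25.5 to 43.4 (edgeR adjusted p = 0.0102 and 0.0478). Vopp1 had 0.989, 0 and 0 counts in WT against 95.8, 25.5 and 15.6 (edgeR adjusted p = 0.0454). Of the 3 calls that the naming rule left out and that were named after their values were seen, 2610008E11Rik was at 0 in every WT library and at 72.8, 35.9 and 14.7 in 5xFAD. Dhx15, a DEAH-box helicase, had 1.30, 1.31 and 1.40 counts in WT and 124, 72.8 and 1.20 in 5xFAD, so its groups overlapped. Gm20459, the 1 lower call, had 35.1, 18.7 and 84.9 counts in WT and at most 0.0163 in 5xFAD (edgeR adjusted p = 0.0103). It shares its locus with 2 other listed genes, and over the summed locus the log2 fold change was -0.53 (SE 0.34; edgeR adjusted p = 0.599), so this call was lost. Over the summed locus of Vopp1 and 1 other gene the log2 fold change was 3.02 (SE 1.06; edgeR adjusted p = 0.286), and that call was lost too. No fold change is given for single genes whose estimates lay near 0 in most libraries of 1 genotype, because such values can be failed estimates.

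**Figure D2:**
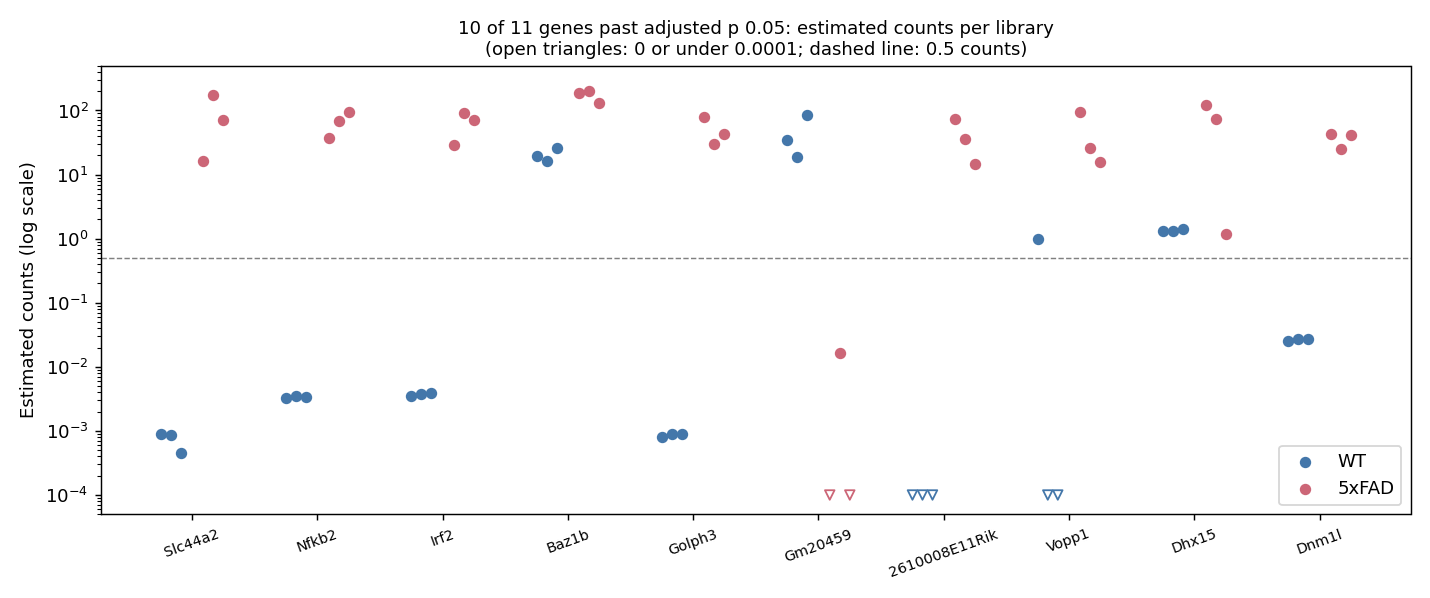
Estimated counts per library on a log axis for 10 of the 11 genes past an adjusted p of 0.05, ordered by p; each point is 1 library, blue for WT and red for 5xFAD. Open triangles mark 0 or values under 0.0001, and the dashed line marks 0.5 counts. Baz1b stands at 16.2 to 26.1 counts in WT, whereas Nfkb2, Irf2, Golph3, Slc44a2 and Dnm1l lie close together far under 0.5 in WT.

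Further genes showed large differences without passing the adjustment. Uri1 and Map3k11 were at or near 0 in WT, with 22.8 to 44.9 and 10.97 to 51.1 counts in 5xFAD (edgeR adjusted p = 0.0625 and 0.0689). In the opposite direction, 10 genes did not pass: Pcdh18, a protocadherin (26.1 to 38.5 counts in WT, at most 0.00332 in 5xFAD; edgeR adjusted p = 0.0610), Bace2, a paralog of the beta-secretase, Gmpr, Timmdc1, Retnla, a marker of alternatively activated macrophages, Sorcs2, Cercam, Pm20d1, Rps18-ps3 and Ccdc126. From Bace2 to Rps18-ps3 these were listed at 0 in all 3 5xFAD libraries, and Retnla had 16.8, 4.02 and 21.8 counts in WT (edgeR adjusted p = 0.245). The loci the file gives for Map3k11, Bace2 and Sorcs2 also hold 39, 12 and 7 listed genes (themselves included), and Rps18-ps3 is a copy of a ribosomal protein gene, so the division of reads is uncertain for these. The same holds for Cox4i1, Vegfa, Aph1a, Hba-a1, Xbp1 and App, named below, whose loci hold 75, 39, 26, 15, 12 and 6 listed genes. Other genes named below share a locus with fewer genes. Among them, the loci of H2-Aa, Itga4 and Ighg2c hold 3 listed genes each. Those of Cd37, Ralgps2, Cox6c, Nr1d1 and Hspa1a hold 2 each.

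The spread within genotypes was wide, with a biological coefficient of variation of 0.815. At an unadjusted p under 0.05, 816 genes were higher and 343 lower (1159 in all, against 483 by chance), and 1767 tested genes (18.3%) had groups that did not overlap, against 10% by chance. The median log2 fold change of all tested genes was 0.11. With quantile normalization the unadjusted split was 557 higher to 538 lower, and limma on those values called 0 genes; limma on log2(FPKM + 1) also called 0, with 1148 genes at an unadjusted p under 0.05 (887 higher, 261 lower). The count of 11 became 67, 4 and 75 without WT replicate 1, 2 or 3, and 3, 18 and 27 without 5xFAD replicate 1, 2 or 3. Baz1b passed in all but 2 of these 6 fits, with edgeR adjusted p = 0.0863 without WT replicate 2 and 0.0829 without 5xFAD replicate 1.

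Genes of MHC class II antigen presentation and costimulation passed the list test as higher in 5xFAD, a call that was lost with an estimated correlation. Here and for the other fixed lists, members were counted as positive or negative by the difference of mean log2(FPKM + 1), 5xFAD minus WT. On this scale the median of all tested genes was itself above 0 (0.24). A majority of positive members is therefore not by itself a shift of a list. All 14 tested members of the MHC class II list had a positive difference, and their summed level went from 1242 ± 262 FPKM in WT to 2383 ± 234 FPKM in 5xFAD (SD, n = 3 each). Cd74, the invariant chain, stood at 471 ± 143 FPKM in WT and 917 ± 110 FPKM in 5xFAD. H2-Aa, the alpha chain of I-A, stood at 196 ± 4.95 and 401 ± 34.9 FPKM, and H2-DMb2, a chain of the peptide-loading chaperone, at 47.4 ± 21.6 and 80.2 ± 19.4 FPKM. For Cd74 and H2-Aa every 5xFAD library lay above every WT library, and the log2 fold changes were 0.84 (SE 0.25) and 0.84 (SE 0.28). The median member differed by 1.01 on the log2(FPKM + 1) scale, against 0.24 for all tested genes, and the list passed limma's camera (adjusted p = 0.00723; adjusted p = 0.649 with an estimated correlation, and 0.0871 by fry). Of the members, 10 were higher at an unadjusted p under 0.05, 7 when adjusted over the list alone, and 0 when adjusted over all genes. The list passed camera with any 1 library left out.

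Genes that mark B cells also stood higher, without passing the list test. All 17 tested members of the B cell identity list had a positive difference, and their sum was 458 ± 55.3 FPKM in WT and 815 ± 218 FPKM in 5xFAD (SD, n = 3 each). Bank1, a scaffold protein of B cell receptor signalling, was at 17.4 ± 3.44 and 55.6 ± 9.40 FPKM (log2 fold change 1.57, SE 0.35; edgeR adjusted p = 0.0689). Ralgps2 was at 4.07 ± 1.21 and 12.7 ± 6.14 FPKM, Cd37 at 54.3 ± 17.1 and 105 ± 53.2 FPKM, and Cd79a at 74.1 ± 18.5 and 121 ± 32.0 FPKM. Camera gave an adjusted p of 0.0558 (adjusted p = 0.649 with an estimated correlation); 8 members were higher at an unadjusted p under 0.05, 2 when adjusted over the list alone and 0 over all genes. The list passed without WT replicate 3 (camera adjusted p = 0.0350) or without 5xFAD replicate 3 (camera adjusted p = 0.00775).

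Endothelial markers, most of which a pure B cell fraction would lack, were plentiful in every library and stood lower beside these lists. Of 12 members, 11 had a negative difference; their sum was 581 ± 71.8 FPKM in WT and 468 ± 46.6 FPKM in 5xFAD (SD, n = 3 each). Vwf, von Willebrand factor, was at 32.9 ± 17.1 and 9.65 ± 6.25 FPKM, the angiopoietin receptor Tek at 20.2 ± 11.4 and 9.52 ± 4.57 FPKM, and Tmem100 at 50.5 ± 12.7 and 27.3 ± 6.84 FPKM. The highest members, Pecam1 and Calcrl, were at 91.0 ± 12.0 and 90.2 ± 14.7 FPKM in WT and at 83.3 ± 41.8 and 74.0 ± 10.9 FPKM in 5xFAD. The list did not pass camera (adjusted p = 0.0674, or adjusted p = 0.649 with an estimated correlation); 3 members were lower at an unadjusted p under 0.05, 2 when adjusted over the list alone and 0 over all genes. The log2 ratio of the summed B cell identity genes to the summed endothelial genes was -0.01, -0.69 and -0.33 in the WT libraries and 0.87, 0.98 and 0.44 in the 5xFAD libraries, a mean difference of 1.11 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 samples can give). The ratio joins lists already seen to differ in opposite directions, so it is no separate test of them.

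**Figure D3:**
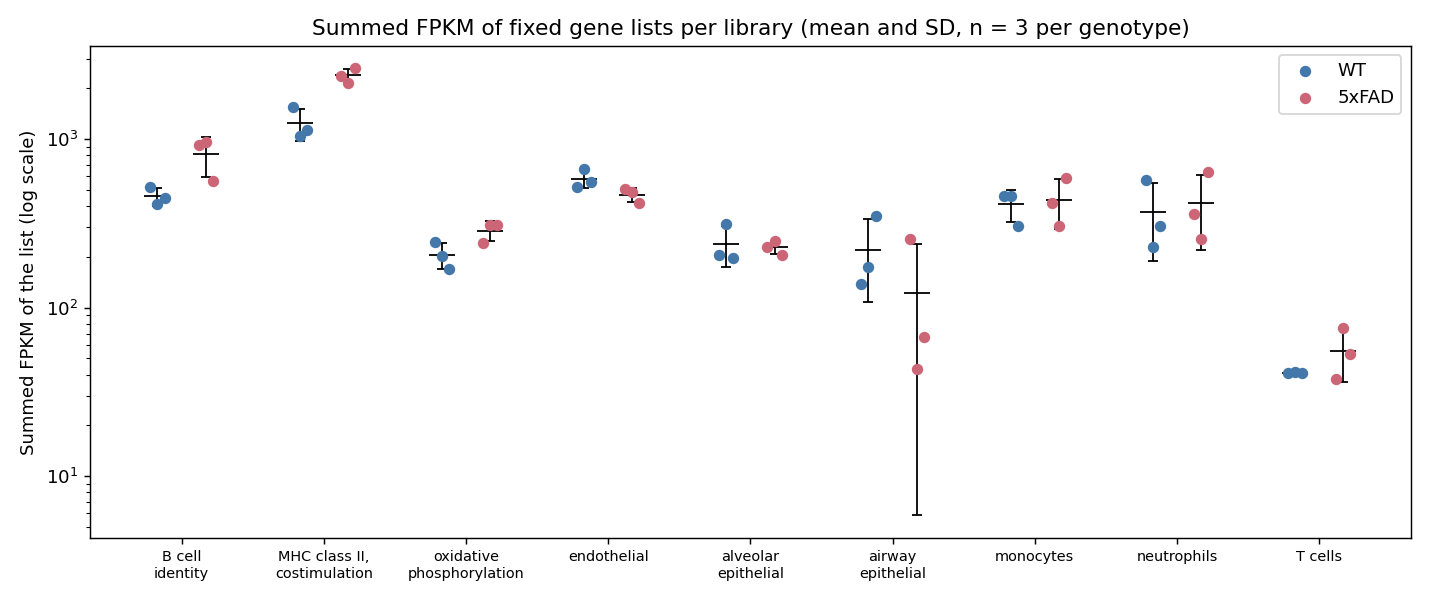
Summed FPKM of 9 fixed gene lists per library on a log axis; points are libraries (blue WT, red 5xFAD), horizontal marks are means and bars are 1 SD (n = 3 per genotype). The sums of the MHC class II list lie higher in every 5xFAD library than in any WT library, and those of monocytes, neutrophils and alveolar epithelial cells overlap between genotypes.

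Oxidative phosphorylation genes passed the list test as higher in 5xFAD. Of 20 members, 17 had a positive difference, with a median difference of 1.16 on the log2(FPKM + 1) scale (camera adjusted p = 0.0150; adjusted p = 0.649 with an estimated correlation). The members with the smallest p were short, weakly detected genes: Cox7c, a subunit of cytochrome c oxidase, was listed at 0 in all 3 WT libraries and at 0.9, 15.5 and 3.2 FPKM in 5xFAD, Ndufs6 was at 0.6, 0 and 0 against 2.5, 12.0 and 2.3 FPKM, and Cox6c at 1.4, 1.4 and 0 against 1.6, 12.8 and 17.2 FPKM. The 2 most abundant members differed little or the other way: Atp5b, the ATP synthase beta subunit, was at 90.2 ± 32.3 and 69.2 ± 16.3 FPKM and Cox4i1 at 28.1 ± 8.96 and 29.6 ± 13.2 FPKM (SD, n = 3 each). At an unadjusted p under 0.05, 3 members were higher, with 0 when adjusted over the list alone and 0 over all genes. The call was lost in 8 of 23 alternatives, among them those without 5xFAD replicate 2 (camera adjusted p = 0.123), after thinning to 1 total (0.101), on log2 CPM (0.0866), from a mean FPKM of 5 (0.0749) and by fry (adjusted p = 0.218). The pathway of the same name in the deposited annotation, with 60 of 95 members positive, did not pass (camera adjusted p = 0.930 over 260 pathways; adjusted p = 0.988 with an estimated correlation).

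Signalling lists of B cells did not pass. In the NF-kB pathway list, 10 of 15 members were positive (camera adjusted p = 0.444); besides Nfkb2, Rel stood at 5.21 ± 2.64 FPKM in WT and 19.2 ± 8.63 FPKM in 5xFAD, and Nfkbie at 2.29 ± 1.91 and 8.94 ± 2.34 FPKM, while Nfkbia was at 26.0 ± 12.6 and 30.9 ± 11.5 FPKM (SD, n = 3 each). Birc3, the most abundant member, was at 31.1, 53.4 and 255 FPKM in the WT libraries and at 49.6, 70.6 and 75.6 FPKM in the 5xFAD libraries. The sum of the list was 269 ± 104 FPKM in WT and 242 ± 27.5 FPKM in 5xFAD. In this list 2 members were higher when adjusted over the list alone and 1, Nfkb2, over all genes. The B cell receptor signalling list had 12 of 18 members positive (camera adjusted p = 0.758). Prkcb, a protein kinase C acting below the receptor, was at 17.9 ± 19.5 and 35.5 ± 13.7 FPKM. It was the 1 member higher when adjusted over the list alone, with 0 over all genes. The 2 most abundant members went opposite ways, Syk at 65.3 ± 27.6 and 111 ± 46.2 FPKM and Inpp5d at 84.3 ± 76.7 and 42.0 ± 12.8 FPKM. Chemokine receptors, integrins and trafficking genes had 14 of 19 members positive (camera adjusted p = 0.579), with Ccr6 at 7.99 ± 2.62 and 23.7 ± 15.4 FPKM and Itga4 at 27.9 ± 4.89 and 46.3 ± 15.1 FPKM. Type I interferon response genes had 13 of 15 members positive (camera adjusted p = 0.424), with Ddx58 at 9.46 ± 7.43 and 24.0 ± 12.5 FPKM. In both of these lists 0 members were called when adjusted over the list alone or over all genes.

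Lists of B cell states gave no call either. Antibody-secreting cell genes split 6 to 6 (camera adjusted p = 0.705), with Xbp1 at 16.7 ± 4.01 and 9.37 ± 5.07 FPKM and Tnfrsf17, the receptor BCMA, at 15.2, 3.7 and 0 FPKM in WT and 0 in every 5xFAD library. Germinal centre genes had 5 of 6 members negative (camera adjusted p = 0.310), of which 1, Mybl1, was lower when adjusted over the list alone. Its groups overlapped, at 32.0, 2.53 and 0 FPKM in the WT libraries and 0, 0 and 0.0932 FPKM in the 5xFAD libraries. B1 and marginal zone genes had 8 of 12 members negative (camera adjusted p = 0.250), with Cd9 at 39.7 ± 5.85 and 17.7 ± 7.77 FPKM and Plac8 at 53.7 ± 26.8 and 27.3 ± 16.7 FPKM. Regulatory B cell and anti-inflammatory genes had 7 of 10 members positive (camera adjusted p = 0.875); Tgfb1 was at 39.2 ± 16.4 and 44.5 ± 27.9 FPKM, and Il10 lay under the expression filter. Pro-inflammatory cytokine genes had 4 of 7 members positive (camera adjusted p = 0.503), with Cxcl2 at 22.6 ± 15.4 and 4.56 ± 2.19 FPKM and Il1b at 31.6 ± 19.6 and 42.2 ± 25.2 FPKM. In the other 4 of these 5 lists 0 members were called when adjusted over the list alone, and over all genes 0 were called in each. Of the immunoglobulin heavy chain constant genes, 1 was tested, Ighg2c, at 47.2 ± 49.6 and 50.4 ± 43.7 FPKM (SD, n = 3 each).

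Among lists of general cell functions, cytosolic ribosomal protein genes had 15 of 20 members positive (camera adjusted p = 0.342), with Rps14 at 41.1 ± 33.0 and 111 ± 9.62 FPKM and Rpl8 at 138 ± 21.3 and 150 ± 14.9 FPKM (SD, n = 3 each). Their sum was 1547 ± 297 and 2092 ± 69.5 FPKM, and many have processed copies in the genome. Heat shock and unfolded protein response genes had 13 of 17 positive (camera adjusted p = 0.579), with Hspa1a at 139.9 FPKM in 5xFAD replicate 3 and at most 33.1 FPKM elsewhere. Immediate-early and dissociation genes had 15 of 20 positive (camera adjusted p = 0.842), with Fos at 67.2 ± 23.5 and 79.7 ± 10.1 FPKM. Circadian clock genes had 7 of 11 members negative (camera adjusted p = 0.124), with Nr1d1 at 7.47 ± 3.10 and 1.38 ± 0.796 FPKM. Glucocorticoid response genes had 8 of 11 members negative (camera adjusted p = 0.124), with Klf9 at 12.1 ± 1.30 and 4.99 ± 2.57 FPKM; the list passed as lower in 1 of 23 alternatives, without 5xFAD replicate 3 (camera adjusted p = 0.0386; with all libraries adjusted p = 0.649 with an estimated correlation). Glycolysis and hypoxia genes split 10 to 9 (camera adjusted p = 0.364), with Vegfa at 44.6 ± 15.8 and 18.3 ± 9.86 FPKM. Cell cycle genes had 8 of 13 negative (camera adjusted p = 0.364), with Mki67 at 6.43 ± 6.96 and 2.88 ± 2.26 FPKM. In each of these 7 lists 0 members were called when adjusted over the list alone or over all genes.

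Genes linked to amyloid clearance and Alzheimer's disease risk did not move one way. Of 19 members 11 were positive (camera adjusted p = 0.875), and 0 were called when adjusted over the list alone or over all genes. Apoe was at 116, 72.1 and 42.3 FPKM in the WT libraries and at 154, 47.0 and 382 FPKM in the 5xFAD libraries, Bin1 at 2.91 ± 1.43 and 12.0 ± 1.12 FPKM, and the gamma-secretase subunit Aph1a at 5.86 ± 2.12 and 1.35 ± 0.946 FPKM (SD, n = 3 each). The mouse genes App and Thy1, which are related to the transgenes, were read as a check of the labels, as far as human reads map to them. App was at 38.0 ± 12.8 FPKM in WT and 38.5 ± 6.72 FPKM in 5xFAD, a difference of 0.05 on the log2(FPKM + 1) scale (exact two-sided permutation p = 0.9). Thy1 was at 0, 0.310 and 0.965 FPKM in the WT libraries and at 2.16, 3.50 and 7.64 FPKM in the 5xFAD libraries (difference 1.86 on the same scale; exact permutation p = 0.1, the smallest that 3 against 3 samples can give). Neither passed edgeR's test over all genes (adjusted p = 0.941 and 0.465). Thy1 is also a member of the fixed T cell list, so its level can reflect T cells in the fraction and is a weak check of the labels.

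None of the lists of other lung and blood cells passed. Monocyte markers summed to 409 ± 89.0 FPKM in WT and 436 ± 143 FPKM in 5xFAD (5 of 10 members positive; camera adjusted p = 0.668), led by Lyz2, lysozyme, at 260 ± 75.0 and 281 ± 146 FPKM (SD, n = 3 each). Neutrophil markers summed to 367 ± 178 and 417 ± 198 FPKM (4 of 9 positive; camera adjusted p = 0.592), led by S100a8 at 161 ± 83.9 and 158 ± 74.1 FPKM; Mmp9, at 17.5 ± 9.90 and 5.20 ± 1.91 FPKM, was lower when adjusted over the list alone, with 0 over all genes. Alveolar epithelial markers summed to 239 ± 65.0 and 227 ± 20.9 FPKM (7 of 12 positive; camera adjusted p = 0.376), with surfactant protein C, Sftpc, at 95.8 ± 47.6 and 111 ± 22.2 FPKM. Airway epithelial markers summed to 220 ± 113 and 122 ± 116 FPKM (3 of 5 negative; camera adjusted p = 0.364); the club cell secretoglobin Scgb1a1, at 162 ± 106 and 52.1 ± 23.8 FPKM, was lower when adjusted over the list alone, and the list passed as lower in 1 of 23 alternatives, without 5xFAD replicate 1 (camera adjusted p = 0.00653; with all libraries adjusted p = 0.649 with an estimated correlation). Fibroblast and smooth muscle markers summed to 211 ± 58.6 and 220 ± 19.4 FPKM (6 of 10 negative; camera adjusted p = 0.758). In the monocyte, alveolar epithelial and fibroblast lists 0 members were called when adjusted over the list alone, and over all genes 0 were called in any of these lists.

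Less abundant cell types gave no call either. T cell markers had 7 of 11 members positive (camera adjusted p = 0.499), with Cd2 at 27.4 ± 8.10 and 22.0 ± 16.3 FPKM and Lck at 1.68 ± 1.21 and 14.9 ± 5.38 FPKM (SD, n = 3 each). NK and innate lymphoid markers had 4 of 7 positive (camera adjusted p = 0.480), macrophage markers 7 of 9 positive (camera adjusted p = 0.758), dendritic cell markers 3 of 4 negative (camera adjusted p = 0.444) and platelet markers 4 of 4 negative (camera adjusted p = 0.124). With the 4 further macrophage markers that the table lists under older symbols, the direction of that list was lower (camera adjusted p = 0.723); the largest of these, Chil3, the chitinase-like Ym1, was at 120 ± 46.4 and 50.4 ± 19.3 FPKM. Among the other macrophage genes Mrc1 was at 5.67 ± 1.15 and 2.30 ± 1.05 FPKM and C1qa at 1.1, 7.1 and 0 FPKM in WT and 15.3, 1.0 and 39.7 FPKM in 5xFAD. In these 5 lists 0 members were called when adjusted over the list alone or over all genes. Lists with under 3 tested members were not put to the test: the mast cell, basophil and eosinophil list, with Gata2 at 12.9 ± 2.47 and 9.27 ± 2.96 FPKM, the mesothelial list, with Krt19 at 23.1 ± 16.97 and 0.673 ± 0.685 FPKM, and the erythroid list. The haemoglobin gene Hba-a1 was listed at 0 in every WT library and at 5.6, 5.8 and 6.4 FPKM in 5xFAD. Camera compares the test statistics of a list with those of all other genes, so its direction can differ from the sign of the median member; it was lower for the antibody-secreting, regulatory B cell, cytokine, glycolysis, amyloid, NK and alveolar epithelial lists although their median member was positive, and for the monocyte, neutrophil and fibroblast lists although their mean was positive.

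The libraries differed widely from each other, within genotypes as well as between them. Pearson correlations of log2(FPKM + 1) across the tested genes averaged 0.573 within WT (0.453 to 0.642, 3 pairs), 0.692 within 5xFAD (0.643 to 0.733, 3 pairs) and 0.553 between genotypes (0.476 to 0.627, 9 pairs). Genes are not independent replicates, and no test was made of these correlations.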

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

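The alternatives that used limma on log2(FPKM + 1), the filterByExpr filter, whole reads, log2 CPM, sums per locus, older symbols or thinned counts, or that left out Lars2 and mitochondrial genes or near-zero estimates, were chosen after seeing the data. The count of 11 genes (10 higher, 1 lower) depended on the setting, and where fewer or more genes or samples entered this changed the test itself; otherwise the cause was not tested. It was 0 (0 higher, 0 lower) by limma with a pseudocount of 0.1, with quantile normalization or on log2(FPKM + 1), and 0 (0 higher, 0 lower) in edgeR with no abundance trend. It was 62 (53 higher, 9 lower) with no filter on low values, 63 (54 and 9) from a mean FPKM of 0.1, 5 (5 and 0) from a mean FPKM of 5, and 7 (6 and 1) with median-ratio scaling. Sample weights gave 56 (42 and 14), DESeq2 63 (55 and 8), and filterByExpr 7 (6 and 1). Leaving out near-zero estimates gave 5 (5 and 0), sums per locus 6 (6 and 0), and leaving out Lars2 and mitochondrial genes 16, of which 4 were lower. At an unadjusted p under 0.05 the limma settings with a count of 0 held 1118 (pseudocount 0.1), 1095 (quantile) and 1148 genes, and edgeR with no trend 1092. Leaving out 1 replicate gave between 3 and 75 genes (3 to 56 higher, 0 to 22 lower): 67, 4 and 75 without WT replicate 1, 2 or 3, and 3, 18 and 27 without 5xFAD replicate 1, 2 or 3. All 11 called genes were kept with no filter, with DESeq2 and after thinning, and 3 were kept without WT replicate 2 and 3 without 5xFAD replicate 1. The share of higher genes at an unadjusted p under 0.05 was 70.4% by edgeR, 77.3% by limma on log2(FPKM + 1) and 50.9% when limma's values were also quantile normalized; the median change of all tested genes was 0.11 by edgeR, 0.24 on log2(FPKM + 1) and 0.01 with quantile normalization.

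Same-numbered libraries of the 2 genotypes did not deviate together (correlations of 0.0004, -0.0043 and -0.0233), and no library correlated best with its own number. The numbers in the titles thus gave no sign of pairing, but correlations this close to 0 cannot exclude that samples were handled in pairs. With the replicate block 26 genes were called (21 higher, 5 lower), the 11 among them, and 2 lists.

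Of the gene lists 2 passed, against 0 with a pseudocount of 0.1 or with an estimated correlation, 4 from a mean FPKM of 0.1, 4 with sample weights and 1 on log2 CPM; leaving out 1 replicate gave 1 to 4. The MHC class II list passed in 20 of 23 alternatives, with adjusted p = 0.0627 at a pseudocount of 0.1, 0.649 with an estimated correlation and 0.0871 by fry. Oxidative phosphorylation passed in 15 (adjusted p from 0.00144 to 0.649), B cell identity in 10 (0.00170 to 0.649) and endothelial cells in 3 (0.0104 to 0.649), each with its direction kept in all 23. Matching 7 list genes by older symbols left 2 lists. By fry 2 lists passed, the NF-kB list among them (adjusted p = 0.0374). The lists were not run with DESeq2, without the abundance trend, with filterByExpr, on whole reads or on sums per locus.

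The difference of Thy1 went from 1.86 to 3.50 on the log2 scale with a pseudocount of 0.1, and the mean correlation within genotypes exceeded that between them in the main setting and in the 14 alternatives in which it was computed, by 0.0309 to 0.120 on the scale of r. Over all alternatives, 2979 fold changes of named genes kept their direction and side of the threshold, 76 lost the threshold, 55 reached it and 142 without a call changed sign; 0 called values reversed. Estimates of 0.5 counts in a library are under 1 read, so depth limits the resolution of weak genes.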

Other observations

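The tests of depth, of shared loci and of other splits of the samples were written down before their results were seen; those on failed estimates, on single calls with a neighbour at their locus, on genes detected per library and on other cells were chosen after.

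Pathways of the deposited annotation were tested as well, and 0 of 260 with 10 to 300 members passed camera (14 at an unadjusted p under 0.05, and 0 adjusted and 2 unadjusted with an estimated correlation). The smallest p belonged to arachidonic acid metabolism, lower with 4 of 19 members positive (camera adjusted p = 0.0726; adjusted p = 0.988 with an estimated correlation). Of 7 list genes that the table holds under older symbols, Jchain, the joining chain of secreted immunoglobulin, was at 37.0 ± 20.2 FPKM in WT and 16.2 ± 11.2 FPKM in 5xFAD (SD, n = 3 each), and Ciart, a clock repressor, at 1.55, 0 and 0 against 3.91, 4.14 and 7.06 FPKM. The sex-linked list did not pass (camera adjusted p = 0.758), and its Y-linked genes separated the libraries within each genotype. Ddx3y, Eif2s3y, Kdm5d and Uty were at 0 estimated counts in WT replicate 3 and 5xFAD replicate 2, while Ddx3y had 57 and 12 counts in WT replicates 1 and 2 and 77 and 13 in 5xFAD replicates 1 and 3.

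The first pattern is that of the calls higher in 5xFAD with almost no WT counts. In 5 of the 10 higher calls (Slc44a2, Nfkb2, Irf2, Golph3 and Dnm1l) all 3 WT estimates lay above 0 and under 0.5, far from any whole read. Condition-wise failed estimates may account for these. In all 5 the estimates varied less between WT libraries (3.19% to 33.7% of the mean) than between 5xFAD libraries (26.6% to 91.6%). That comparison cannot tell failed estimates from genes absent in WT, because counts of expressed genes vary between 5xFAD samples in either case. Baz1b argues against failed estimates for itself, with a lowest WT estimate of 16.2 counts, and the others, 2610008E11Rik, Vopp1 and Dhx15 among them, stay open. A depth difference between the genotypes was excluded as the whole cause, since all 10 passed after thinning to 1 total. Reads given to a listed neighbour at the same locus cannot be judged for the 10 calls together: 6 passed when counts were summed over the locus, but 6 of the 10 have no listed neighbour, so that summing leaves their counts as they were. Of the 4 with a neighbour, 3 passed over the locus, which argues against this as their whole cause. For Vopp1 it stays open, since with the counts of its neighbour added the locus had 15.8, 4.02 and 0 counts in WT and 104, 30.3 and 17.4 in 5xFAD, and the call was lost (log2 fold change over the locus 3.02, SE 1.06; edgeR adjusted p = 0.286). For Gm20459, the lower call, it stays open as well: its locus had 227.4, 296.3 and 247.5 counts in WT and 207.5, 172.1 and 184.4 in 5xFAD, and the call was lost (log2 fold change over the locus -0.53, SE 0.34; edgeR adjusted p = 0.599), as the rest of its locus held most of the reads in both genotypes. The design cannot give a share of splits under 0.05: the real split gave 11 genes, the highest other split 5, and 1 of 10 splits gave as many as the real one, itself; a difference of genotype remains open and untested for these genes.

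The second pattern is a lopsided absence: 568 genes had 0 rounded counts in all WT libraries and some in all 5xFAD libraries, and 22 the reverse, while the highest of the other groups of 3 libraries gave 152. A depth difference between the genotypes would leave a ratio under 2 once the totals without Lars2 are made equal, but after thinning these to 341200 counts there were 500 against 27 genes, a ratio of 18.5. Fewer genes detected per WT library did not account for it alone, because putting 5xFAD replicate 1 in place of WT replicate 2, which detected about as many genes (10490 and 10381), left 87 genes, so that the real group held 6.53 times as many. The genes were weak, with a median of 4.40 counts in 5xFAD, and 90.5% of them were at exactly 0 in every WT library. Failed estimates, a difference in handling between the genotypes and a difference of genotype stay open and were not tested.

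The third pattern is the higher level of MHC class II genes, which passed the list test (camera adjusted p = 0.00723; adjusted p = 0.649 with an estimated correlation), and of B cell identity genes beside lower endothelial genes, which did not pass. A lower share of other cells in the 5xFAD libraries is a candidate explanation, as magnetic selection leaves some other cells behind; it predicts that markers of all other types are lower to a like degree. On the log2(FPKM + 1) scale 7 of 11 lists of other cells had a median under 0, from -1.17 for airway epithelium to 0.24 for T cells. Their 93 members did not differ between lists beyond chance (permutation p = 0.105), which decides neither way. The median edgeR log2 fold change instead ran from -2.04 for platelets to 0.67 for macrophages, and was 0.44 for airway epithelium. Of 4 abundant markers, Lyz2 was at 260 ± 75.0 and 281 ± 146 FPKM, S100a8 at 161 ± 83.9 and 158 ± 74.1 FPKM, Sftpc at 95.8 ± 47.6 and 111 ± 22.2 FPKM and Scgb1a1 at 162 ± 106 and 52.1 ± 23.8 FPKM (SD, n = 3 each). Chil3, held under an older symbol and so absent from the macrophage list of this test, was at 120 ± 46.4 FPKM in WT and 50.4 ± 19.3 FPKM in 5xFAD. Siglecf and Plet1, absent likewise, were lower too, and Adgre1 was higher. With these markers the direction of the macrophage list was lower (camera adjusted p = 0.723). MHC class II genes are also expressed by dendritic cells and macrophages. For the lists, too, the splits are too few for a share under 0.05: the real split gave 2 lists, the highest other split 3, and 7 of 10 gave at least as many; cell makeup and a difference of genotype cannot be told apart here.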
